A study of Homo sapiens with 5 samples.

How the data were processed

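Total RNA of 1 pool of insulin-resistant human vastus lateralis muscle was hybridised to 5 Affymetrix arrays, Hu35K subA to subD and HuFL, per the labels. The labels give pool number 5 and no further treatment. All 5 arrays were assigned to 1 group from the sample titles and counted as 1 biological replicate, because they read the same RNA pool, mostly with different probes.

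Each deposited table gives 1 intensity per probe set. The labels used here state neither the scanner software nor the scaling or normalization behind these values, so these are not given in the sources used here. The values were whole numbers on a linear scale, and between 23.7% and 31.5% of them per array were below 0, so no logarithm was taken of the full tables. That pattern is like that of perfect-match minus mismatch differences, a reading of the values only. No genome build was named, and no coordinates are given. No column of another series was used (0 columns).

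Probe sets were paired with genes through the platform annotation, dated 2016, and symbols were looked up by gene number in RefSeq names of assembly GRCh38.p14, used for names only. Pairing with 1 gene succeeded for 7564 probe sets of subA, 5108 of subB, 5755 of subC, 5650 of subD and 5709 of HuFL, and 0 symbols had to be replaced. Only these probe sets name a gene, and probe sets for the opposite strand were left out. The remaining probe sets are unnamed here, which does not mean that they lack a gene. Genes of the Y chromosome were not reported.

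Background was measured on each array from its values below 0. Their root mean square gave a noise SD of 326 on subA, 76.5 on subB, 99.0 on subC, 132 on subD and 458 on HuFL, and a probe set above 3 noise SDs was called above background. This assumes that unbound probe sets scatter evenly around 0, which some control probe sets did not do, as the closing section reports. A gene was called above background when any of its probe sets was. For arrays, depth is not a count of molecules, and the number of arrays limits the precision. Medians of all values were 104, 14, 21, 39 and 48 on the arrays in the same order.

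A gene's score was the median percentile of its probe sets, each ranked within its own array, so that arrays of different brightness could be joined. The 32 gene lists held 583 different genes, of which 519 were measured. The lists covered thick and thin filaments, slow and fast fibres, Z-disc, calcium handling, myogenic factors, phosphagen and oxygen stores, complex I, complexes II to V, citric acid cycle, glycolysis, glycogen, insulin signalling, glucose entry, fatty acid oxidation, fatty acid uptake, mitochondrial regulators, ribosome, proteasome, stress and inflammation. They also covered markers of adipocytes, erythrocytes, endothelium, fibroblasts, smooth muscle, macrophages, lymphocytes and nerve, and genes of liver, brain, and pancreas and germ cells. Each list's median score was placed among 10000 random lists of the same size, matched on the number of probe sets per gene (1, 2, 3 or at least 4). A percentile of 97.5 or more was called high and one of 2.5 or less low. With 1 sample and no comparison group no test between groups exists, and these percentiles describe the arrays and are not p-values.

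Named genes followed a rule. In each list the 3 genes with the highest and the 1 with the lowest score were named, on each array the 5 brightest named probe sets, and in addition a panel of 16 genes of insulin action and muscle metabolism, of which 15 were measured. The naming rule, the lists, the main analyses and most alternatives were fixed before the data were examined, and the closing section says which of its tests were not.

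Brightness was compared on control probe sets listed on all 5 arrays and above background on each, by the coefficient of variation over arrays and by each array's median log2 ratio to the mean over arrays. Scores from HuFL and from the Hu35K arrays were correlated across genes by Pearson's r and Spearman's rho with 100000 permutations, two-sided. Other alternatives were a bound of 2 noise SDs, a bound at the mirrored percentile 1 of the values below 0, scaling to a trimmed mean (2% trimmed), each array left out, the highest probe set per gene, each array kind alone, leaving out probe sets with a suffix for shared or special design, unmatched random lists and the list mean. Alternatives added after seeing the data were a bound from the median of the values below 0, leaving out the lowest value of each array, leaving out values of 0, leaving out control probe sets, and leaving out IDs shared by both array kinds.

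The calculations were tested on simulated data. Among 40 simulated lists of 15 unchanged genes 3 were called, and among 40 lists of shifted genes 28 were called high, with 14746 genes in that step. For the background bound, 10 of 8010 simulated unbound probe sets and 856 of 890 bound ones were called, and a noise SD of 100 was recovered as 102. The simulated noise was normal around 0. On the real arrays the values below 0 had longer tails. Their root mean square gave a noise SD of 326 on subA and 458 on HuFL, while their median gave 130 and 133. The simulated call rates therefore need not hold for these arrays. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.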

Results

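Total RNA from human vastus lateralis, a thigh muscle, was measured on short-oligonucleotide expression arrays. The labels describe 1 RNA pool of insulin-resistant muscle, and this pool was read on 5 arrays. Of these, 4 belong to the Hu35K set, subA to subD, which was designed largely from expressed sequence tags, and HuFL holds mostly full-length human genes. The arrays carry mostly different probe sets, short groups of probes for 1 transcript, and read the same RNA pool. The 5 readings together therefore form 1 biological sample with no replicate. No group was set against another, and insulin-sensitive muscle was not analysed here. Values are deposited intensities, and every level given for a gene is 1 reading on 1 array. Their number limits the precision. Probe sets differ in how strongly they bind, so a gene's percentile or rank describes its reading within its own array and is not a measure of transcript amount relative to other genes.

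The arrays held 42843 probe sets, of which 29786 were paired with 1 gene, 857 with several genes and 12200 with none. A score could be given to 14746 genes, as the median percentile of a gene's probe sets within their arrays. Of these genes, 2002 (13.6%) had at least 1 probe set above background. By array, 543 of 8934 probe sets on subA lay above background, 508 of 8924 on subB, 621 of 8928 on subC, 1048 of 8928 on subD and 352 of 7129 on HuFL. These shares were 6.08%, 5.69%, 6.96%, 11.7% and 4.94%. The background bound was 978 on subA, 230 on subB, 297 on subC, 397 on subD and 1374 on HuFL. Values equally far below 0 numbered 48, 62, 45, 55 and 13 on the same arrays. Probe sets of BioB, a bacterial spike control, read 397 to 483 on subA and 534 to 751 on HuFL, below the bounds there. They were above background on subB and subD. A reading below the bound on subA or HuFL therefore need not mean that a transcript was absent. A bound from the median of the values below 0, chosen after seeing the data, raised the counts to 1788, 1489, 2150, 2358 and 1200, and the genes above background to 5250 (35.6%). On HuFL a single value of -14061 set much of the bound, which was 913 without it, with 520 probe sets above, a setting also chosen after seeing the data. The number of members above background moved by over 1.5 times in 18 of the 32 gene lists with the first of these bounds and in 3 with the other, and such counts are given beside each list.

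The first question was which gene groups of muscle the pool's RNA held at levels above background. Genes of the contractile apparatus were among the brightest readings. Of 23 measured genes of the thick and thin filaments, 17 were above background, and the list's median score of 97.6 exceeded all 10000 random lists (percentile 100). TNNC1, the calcium-binding troponin of slow muscle and heart, read 17379 on HuFL. TNNT1, slow troponin T, read 14703 on HuFL and 8014 on subC, the highest reading of that array. MYBPC2, the fast myosin-binding protein C, read 14942 on HuFL and 10202 on subD.

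Markers of both fibre types were bright. Of 9 slow-fibre genes 7 were above background, with a median score of 97.2, and of 12 fast-fibre genes 10 were, with a median score of 99.8. Both lists had a percentile of 100. TNNI1, slow troponin I, read 9444 on HuFL and 1001 on subC. ATP2A1, the calcium pump of fast fibres, read 18653 on HuFL, the highest value of that array. PVALB, a calcium buffer of fast fibres in small mammals, read 147 on HuFL and was not above background. The slow and fast lists share 8 and 11 of their measured members with other lists, mostly the filament list, so these are not separate lines of evidence, and the 2 medians were not tested against each other.

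Genes of the Z-disc and cytoskeleton reached a median score of 98.6 (percentile 100), with 10 of 13 above background. MYOZ1, a Z-disc protein that binds calcineurin, read 9122 on subA and 5045 on subB. TCAP, which anchors titin, read 8644 on subD, and CRYAB, a small heat-shock protein that protects desmin, read 11078 on HuFL. SGCB, a sarcoglycan of the muscle membrane, read 53 and 92 and was not above background. Calcium handling and excitation had a median score of 96.1 (percentile 100) and 11 of 18 members above background. CASQ1, the calcium store protein of the sarcoplasmic reticulum, read 6235 on subC, and SLN, a small inhibitor of the calcium pump, read 8588 on HuFL. CHRNA1, a subunit of the acetylcholine receptor at the nerve contact, read -46.

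Some of the best known muscle genes gave no usable reading. MYL2, the slow regulatory light chain, was listed at 0 on HuFL, its only probe set. The same held for ACTA1, the skeletal muscle actin, MYBPC1, CA3 and CKM, the muscle creatine kinase, 4 genes singled out after their values were seen. HuFL listed 1056 probe sets at exactly 0, which is 14.8% of the array, so a value of 0 on HuFL was not read as absence. Genes listed only at 0 stay among the measured members of each list.

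Of 11 measured regulators and markers of the muscle lineage, 2 (18.2%) were above background, next to 13.6% of all scored genes. These shares were not matched on probe sets per gene, of which the 11 genes had 32. The median score of 63.3 lay at percentile 82.4, inside the random range. The bound from the median of the values below 0, the median-based bound in what follows, put 4 above. MYOD1, MYF6 and MYOG, named after their values were seen, were listed only at 0, and without values of 0 the other 8 genes lay at percentile 90.3. MEF2C and MEF2D, transcription factors of differentiated muscle, were those 2. MEF2C read 5252 on subD and 766 on subC, above background, and 925 and 0 on HuFL. MEF2D read 784 on subD and 558 on subB, above background, and 707 on subA and 196 on subC. CDH15, a cadherin of muscle precursor cells, read 337. PAX3, a factor of muscle progenitors, ranged from -389 to 54 over 6 probe sets. MSTN, which encodes the growth inhibitor myostatin, read 62 on subC and was not above background.

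**Figure D1:**
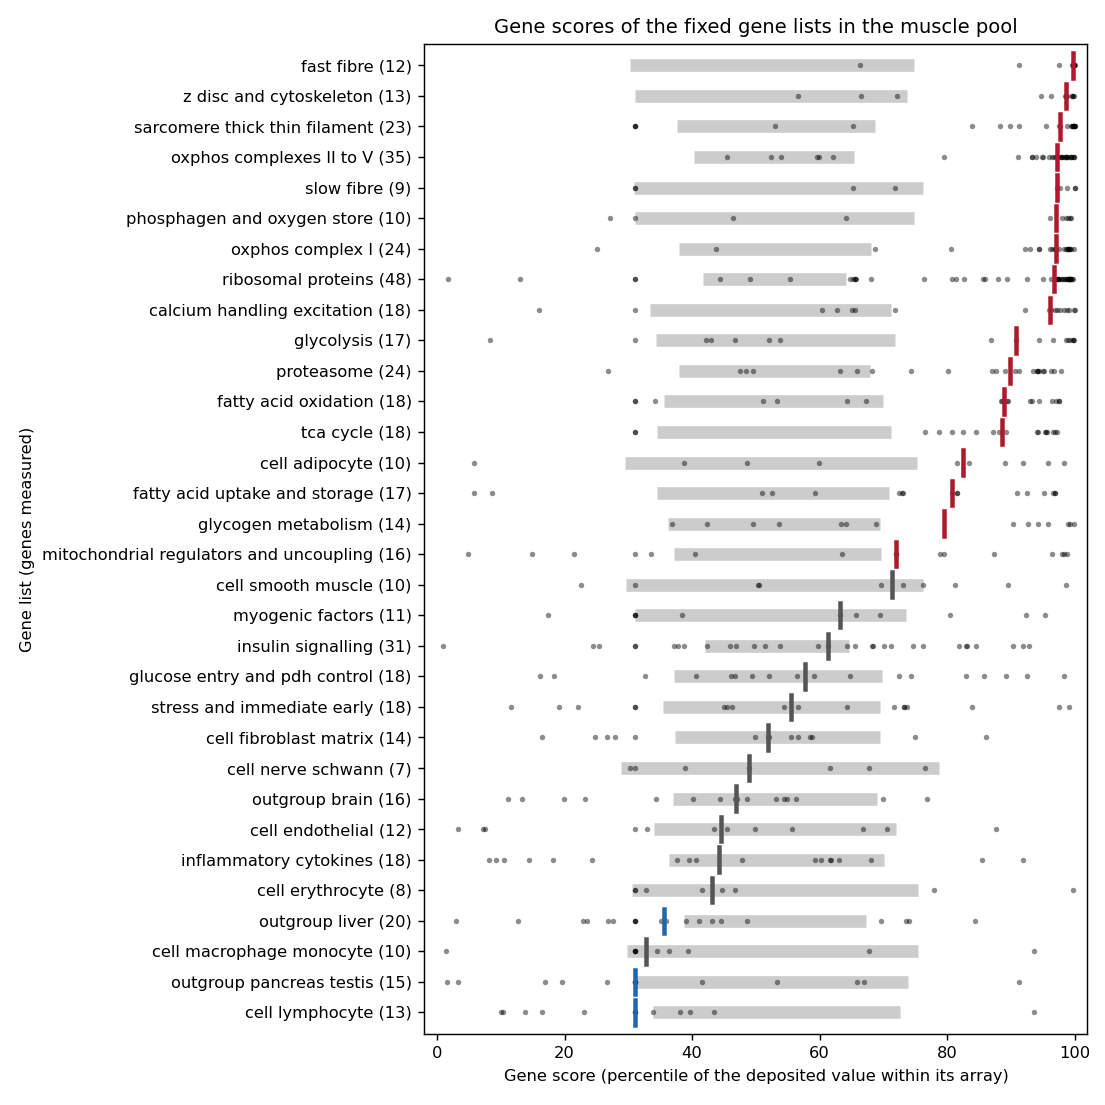
Each black point is the score of 1 measured gene, the median percentile of its deposited values within their arrays (horizontal axis, 0 to 100), for 32 gene lists (vertical axis, number of measured genes in parentheses). Thick ticks are list medians, red for 17 lists above the random range, blue for 3 below and grey for 12 inside, and light bars span the central 95% of 10000 random lists.

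Energy metabolism was the next question. The phosphagen and oxygen-store list had 8 of 10 members above background and a median score of 97.0 (percentile 100). MB, the oxygen store myoglobin, read 9561 on HuFL. CKMT2, the mitochondrial creatine kinase of muscle, read 8277 on HuFL, and ADSS1, the muscle enzyme of the purine nucleotide cycle, read 5494 on subD and 3845 on subA. SLC6A8, the creatine transporter, ranged from -838 to 914 over 3 probe sets, none of them above background, although the reading of 914 passed the HuFL bound of 913 that leaves out the single lowest value.

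Respiratory chain genes were nearly all detected. In complex I, 21 of 24 measured genes were above background (median score 97.0, percentile 100), and in complexes II to V with cytochrome c it was 32 of 35 (median score 97.3, percentile 100). NDUFA1, a small complex I subunit, read 11347 on subA. NDUFS6 read 1049 on subB, and NDUFA8 read 2691 on subA and 2245 on subB. UQCRQ of complex III read 10866 on subA, COX7A1, the muscle and heart form of a cytochrome oxidase subunit, read 13078 on HuFL, and ATP5ME of the ATP synthase read 6875 on subA. NDUFB2 read 8 and -7, and CYCS, cytochrome c, read 37 on subC and was listed at 0 on HuFL.

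In the citric acid cycle with pyruvate dehydrogenase, 10 of 18 measured genes were above background, with a median score of 88.7 (percentile 100), and 16 passed the median-based bound. SDHA, which links the cycle to the respiratory chain, read 3167 on HuFL. MDH2, the mitochondrial malate dehydrogenase, had 4204 on subD and 1519 on subA, both above background, while another of its probe sets read 610 on subA and was not. PDHA1, the catalytic subunit of pyruvate dehydrogenase, read 2216 on HuFL. IDH2 was listed at 0 on HuFL, its only probe set.

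Glycolysis had 10 of 17 genes above background (median score 90.7, percentile 100). Outside the control probe sets GAPDH read 11363 on HuFL, 7939 on subA and 3500 on subC, while a probe set on subD read 161. Also on HuFL, ENO3, the muscle enolase, read 12183 and ALDOA, the muscle aldolase, 12064. PFKP, the platelet form of phosphofructokinase, ranged from -216 to -17. Glycogen metabolism had 9 of 14 genes above background and a median score of 79.6 (percentile 99.9). PYGM, the muscle glycogen phosphorylase, read 5856 on subD and 5497 on HuFL. PGM1, which interconverts glucose phosphates, read 9499 on HuFL, and PPP1R3C, a subunit that targets protein phosphatase to glycogen, read 3231 on subB. PHKG2, the liver form of a phosphorylase kinase subunit, read 55 and -202. On HuFL alone the glycogen list lay at percentile 90.6, inside the random range.

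Of 31 measured insulin signalling genes, 5 (16.1%) were above background, next to 13.6% of all scored genes, and the median score of 61.4 lay at percentile 92.3, inside the random range. Unlike the percentile, these shares were not matched on probe sets per gene, of which the 31 genes had 105. GRB10, an adaptor that dampens signalling from the insulin receptor, read 555 on subC and 620 on subD, both above background, and 792 on HuFL, below that array's bound. IRS2, an adaptor downstream of the receptor, read 993 on subA, close to the bound of 978, and 212 on subC. GSK3A, a kinase that inhibits glycogen synthase, read 188 on subB and 578 on HuFL and was not above background. The other members above background, named after their values were seen, were PTPN1, a phosphatase that acts on the receptor (883 on subB), the adaptor GRB2 and the kinase GSK3B. EIF4EBP1, a repressor of translation that insulin relieves, read -219. The receptor INSR gave readings from -69 to 164 over 7 probe sets and its adaptor IRS1 from -88 to 642 over 6, with none above background. PIK3R1, the regulatory subunit of the lipid kinase of this pathway, read 18 to 275, and AKT2, the insulin-responsive kinase of muscle, -38 to 459. RRAD, a small GTPase studied in diabetic muscle, read 167. With the median-based bounds of 391 on subA, 89.0 on subC and 400 on HuFL, several of these genes had a reading above. They were IRS1 (642 on subA), INSR (120 on subC), AKT2 (459 on HuFL) and GSK3A (578 on HuFL). PIK3R1 and RRAD did not pass. With HuFL alone the list lay at percentile 98.99, above the random range, and the count above background was 10 with a bound of 2 noise SDs, 2 with the mirrored percentile and 17 with the median-based bound.

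Glucose entry and the control of pyruvate oxidation had 4 of 18 genes above background, 11 with the median-based bound, and a median score of 57.7 (percentile 70.1). MPC1, a subunit of the mitochondrial pyruvate carrier, read 2121 on subA. PDP1, the phosphatase that activates pyruvate dehydrogenase, read 331 on subB, above background, and 624 on subA, which was not. MPC2, the partner of MPC1, and the AMPK subunit PRKAA2 were also above background and were named after their values were seen. PRKAG1, a subunit of the energy sensor AMPK, read 644. The insulin-responsive glucose transporter SLC2A4 read 338 on subA and 393 and 846 on HuFL, with none above background. HK2, the hexokinase of insulin-sensitive tissue, ranged from -3 to 227, PDK4, the kinase that inactivates pyruvate dehydrogenase, from -43 to 594, and GYS1, glycogen synthase of muscle, read 905 on HuFL, all below their bounds. SLC2A4 (846 on HuFL), GYS1 (905 on HuFL) and PDK4 (594 on subA) passed the median-based bounds, 400 on HuFL and 391 on subA. HK2 did not. SLC2A5, a fructose transporter, ranged from -54 to 669. Scored by the highest probe set of each gene, the list lay at percentile 98.6, above the random range.

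Lipid metabolism was read in a pair of lists. Fatty acid oxidation had 9 of 18 genes above background, 14 with the median-based bound, and a median score of 88.9 (percentile 100). ACAT1, which acts at the last step of oxidation and in ketone use, read 3751 on HuFL, ACADM, the medium-chain acyl-CoA dehydrogenase, 3721 on HuFL, and ECI1, which prepares unsaturated fatty acids, 2253 on subA and 1679 on HuFL. HADH was listed at 0 on HuFL. CPT1B, the muscle carnitine palmitoyltransferase, had no probe set paired with it alone. In fatty acid uptake and storage 4 of 17 genes were above background, 11 with the median-based bound, with a median score of 80.8 (percentile 99.9). FABP3, the fatty acid binding protein of muscle and heart, read 2673 on HuFL. CD36, a fatty acid transporter, read 2603 on HuFL and 781 on subB, both above background, and 1194 on a further HuFL probe set, which was not. SLC27A1, another transporter, read 319 on subB, and ACSL1, which activates fatty acids and was named after its value was seen, 1438 on HuFL. LIPE, hormone-sensitive lipase, ranged from -738 to 289, and LPL, lipoprotein lipase, read 363. By highest probe set per gene the uptake list lay at percentile 93.1, inside the random range.

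Mitochondrial regulators and uncoupling had a median score of 71.9 (percentile 98.7) and 5 of 16 genes above background, 9 with the median-based bound. VDAC1 and VDAC3, channels of the outer mitochondrial membrane, read 5697 on HuFL and up to 2383 on subB, and VDAC2, named after its values were seen, was above background as well. SOD2, the mitochondrial superoxide dismutase, read 1962 on subA, 1783 on subD and 510 on subB, while 2 probe sets on subC read 74 and 44. PPARGC1A, a coactivator of mitochondrial biogenesis, read 860 on subD by a probe set of shared design, above background. Its other probe sets read 209 on subD and 101 on subC and were not. Of the transcription regulators on the list, only PPARGC1A was above background. The others scored from 14.9 (NRF1) to 78.8 (ESRRA), both named after their values were seen. The list's call is therefore not one about regulators alone. The uncoupling protein UCP3 read 359 and 543 on HuFL and 371 on subD, with none above background, and UCP2 read -256. The UCP3 readings of 543 and 371 passed the median-based bounds, 400 on HuFL and 151 on subD. This list fell inside the random range in 4 settings, at percentile 96 by highest probe set, 93.2 on HuFL alone, 88.3 on the Hu35K arrays alone and 93 by the list mean.

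Protein synthesis and breakdown were read next. Of 48 measured ribosomal protein genes 44 were above background (median score 96.7, percentile 100). RPL30 read 8294 and RPL13A 5563 on subD, and RPL32 read 10352 on HuFL. RPS27 read 12073 on subA, and RPS20 read 11372 and RPL41 10905 on subD. RPL28 read -169 on subC. RPS27 and RPL41, both bright on Hu35K arrays, were listed at 0 on HuFL. Ribosomal genes have many near-identical processed copies in the genome, so their readings are uncertain. The proteasome list had a median score of 89.9 (percentile 100). Its count above background depended on the bound, with 7 of 24 under the main bound, 17 without the single lowest HuFL value and with a bound of 2 noise SDs, and 23 with the median-based bound. PSMA4 read 2709 on HuFL and 2383 on subD, PSMB6 2488 and PSMC1 2053 on HuFL, and PSMB7 ranged from -15 to 892. The Hu35K arrays alone put the proteasome list at percentile 59.1, inside the random range.

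Stress and inflammation lists lay inside the random range. Stress and immediate early genes had 5 of 18 members above background and a median score of 55.5 (percentile 62.3). HSPB1, a small heat-shock protein abundant in muscle, read 12062 on subD and 8908 on HuFL and, by another subD probe set, 136, and MT2A, a metallothionein, read 3681 on HuFL. IER2 read 1149 on subD, above background, with 421 on HuFL and -1 on subD by further probe sets. Also above background were JUN and MT1X, named after their values were seen, while IER3 read -95. Inflammatory genes had 1 of 18 members above background, 2 with the median-based bound, and a median score of 44.2 (percentile 16.0). That member was IKBKB, a kinase that activates NF-kappaB, at 392 on subB, with 51 by another subB probe set. NFKBIA, the inhibitor of NF-kappaB, read 843, IL10 read 164, and SOCS1, a brake on cytokine signalling, ranged from -168 to 31.

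A muscle sample also holds blood, vessels, fat, nerve and connective tissue, and fixed marker lists measured these. Adipocyte markers had a median score of 82.5 (percentile 99.6), the only list of another cell type above the random range, with 3 of 10 above background and 5 with the median-based bound. CFD, the serine protease adipsin, read 2336 on subA and 1766 on HuFL by 1 probe set and -265 on subA by another. GPD1, which makes glycerol phosphate in fat and is also active in muscle, read 2243 on subA, PLIN1, the lipid droplet coat protein, named after its value was seen, read 422 on subD, and FABP4, the fatty acid binding protein of fat cells, read 848 and was not above background. Of the 10 members, 2 are also in the uptake and storage list. The call was lost by highest probe set, at percentile 97.3, and on the Hu35K arrays alone, at 90.6.

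Smooth muscle and pericyte markers had 3 of 10 above background and a median score of 71.4 (percentile 93.3), and they lay at percentile 98.6 without probe sets of shared or special design. DES, which skeletal muscle also expresses and which is also in the Z-disc list, read 6578, and RGS5, a pericyte marker, read up to 2314 on subA. MYH11, smooth muscle myosin, named after its values were seen, read 1024 on subD, PDGFRB 354 and ACTG2 -6. Endothelial markers had 2 of 12 above background, 4 with the median-based bound and 1 with the mirrored percentile (median score 44.5, percentile 19.97). VWF read 847 on subD, above background, and 335 on HuFL, which was not. EGFL7, named after its values were seen, read 556 on subD, above background, TEK ranged from 72 to 261, FLT1 was listed at 0 to 346, and KDR read -368. Fibroblast and matrix genes had 3 of 14 above background and 9 with the median-based bound (median score 51.9, percentile 47.3). The 3 were COL1A2, DCN and SPARC, picked out after their values were seen. Others lay below their bounds, with LUM at 496, COL6A2 from -73 to 286, FBN1 from 3 to 425 and COL5A1 at -14 and -62. Nerve and Schwann markers had 0 of 7 above background, 2 with the median-based bound (median score 48.9, percentile 39.5). Here MBP, a myelin protein, ranged from -41 to 212, SOX10 read 91, NGFR 113 and S100B 82 and -53.

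Blood cell markers were mostly not above background. Erythrocyte genes had 2 of 8 above it, 3 with the median-based bound (median score 43.1, percentile 20.9). HBA2, an alpha-globin, read 3997 on subC by a probe set of shared design, and ALAS2, the haem synthesis enzyme of red cells, read 662 on subD, with 428 on subA, 79 on subC and -31 on HuFL below their bounds. EPB42 read 35, and HBD and, singled out afterwards, HBB were listed only at 0, and without values of 0 the other 6 genes lay at percentile 44.0. Macrophage and monocyte markers had 0 of 10 above background (median score 32.8, percentile 5.12). Of these, CD163, CSF1R and S100A8, named after their values were seen, were listed only at 0, and without values of 0 the other 7 lay at percentile 8.18. Lysozyme, LYZ, read up to 1058 on HuFL and passed the bound of 913 that leaves out the single lowest HuFL value, giving 1 of 10 there and with the median-based bound. In the same list AIF1 read 161, MRC1 4 and CD14 -564. Lymphocyte markers had 0 of 13 above background and a median score of 31.1 (percentile 1.02), below the random range. That call was lost on HuFL alone and without probe sets of shared or special design, as given in the next paragraph. Of the T-cell receptor components, CD3E read 1035 and CD3D 179 on HuFL, and CD3D -25 on subD. CD3E passed the HuFL bound of 913, giving 1 of 13, and 2 passed the median-based bound. The co-receptor CD8A read 94 on subA and was listed at 0 on HuFL, and the B-cell gene CD79B ranged from -628 to 12.

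Genes of organs that were not sampled were read for reference. Liver genes had 3 of 20 (15%) above background (median score 35.5, percentile 0.9), and genes of pancreas and germ cells had 0 of 15 (median score 31.1, percentile 2.26). Brain genes had 3 of 16 (18.8%; median score 46.9, percentile 24.7). The liver and brain shares were not below the 13.6% of all scored genes. That share was not matched on probe sets per gene, and a gene counts when any of its probe sets passes. The 20 liver genes had 50 probe sets and the 16 brain genes 35. HP and TAT of the liver list and REG1A, TNP1 and PGK2 of the pancreas and germ cell list, named after their values were seen, were listed only at 0. With the median-based bound the counts were 5, 1 and 7. Above background were APOC3 at 690 on subD and F2 at 306 on subB among liver genes, and SYN1 at 767 on subD among brain genes, and, named after their values were seen, TTR (liver), CAMK2A and MAG (brain). Further probe sets of the first 3 were not above background, with APOC3 at 244, F2 at 297 and 0, and SYN1 at 64 and 0. FGG read 230, APOA1 -404 to 0, TH 168 and 310, SYP 234 and 0, GRIN1 -101, SST 777, ACRV1 134 and 304, ZP2 144 and PRM2 -549, with none above background. A score of 31.1 is that of a HuFL value of 0. With all values of 0 left out, a setting chosen after seeing the data, the lymphocyte, liver and pancreas and germ cell lists stayed low, at percentiles 2.17, 0.6 and 1.3. They lost the call on HuFL alone, at 7.05, 6.88 and 5.66, and without probe sets of shared or special design, at 2.63, 4.91 and 4.22, and the liver list also on the Hu35K arrays alone, at 5.18. Of the 32 lists, 17 were high, 3 low and 12 inside the random range. For 32 random lists 1.6 would lie outside. The fixed lists share members and are not random draws, so this number is a reference and not a test.

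The brightness of the arrays was measured on control probe sets listed on all 5. Of 59 such IDs, 13 were above background on every array and read the strand of the transcript, 6 for bacterial transcripts and 7 for human sequences, 3 each for GAPDH and ACTB and 1 for the Alu repeat. GAPDH, read toward its 3 prime end, gave 9992 on subA, 4231 on subB, 4881 on subC, 9342 on subD and 10440 on HuFL. The median coefficient of variation over the arrays was 37.8% ± 2.75 (SD over 13 control probe sets), from 33.7% to 43.2%. On the log2 scale the arrays lay at 0.42 (subA), -0.88 (subB), -0.63 (subC), 0.20 (subD) and 0.36 (HuFL) from their mean, a 2.46-fold range. After each array's shift was removed, the residual SD was 0.13 (log2), or 1.09-fold. When the arrays were scaled to the same trimmed mean the order was mostly turned over, with subB at 0.68, subC at 0.14, subD at -0.08, subA at -0.57 and HuFL at -0.61, so that subA stayed above HuFL. The arrays carry mostly different probe sets, so equal trimmed means need not mean equal brightness. Without subB the range was 2.08-fold and the coefficient of variation 29.5%.

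**Figure D2:**
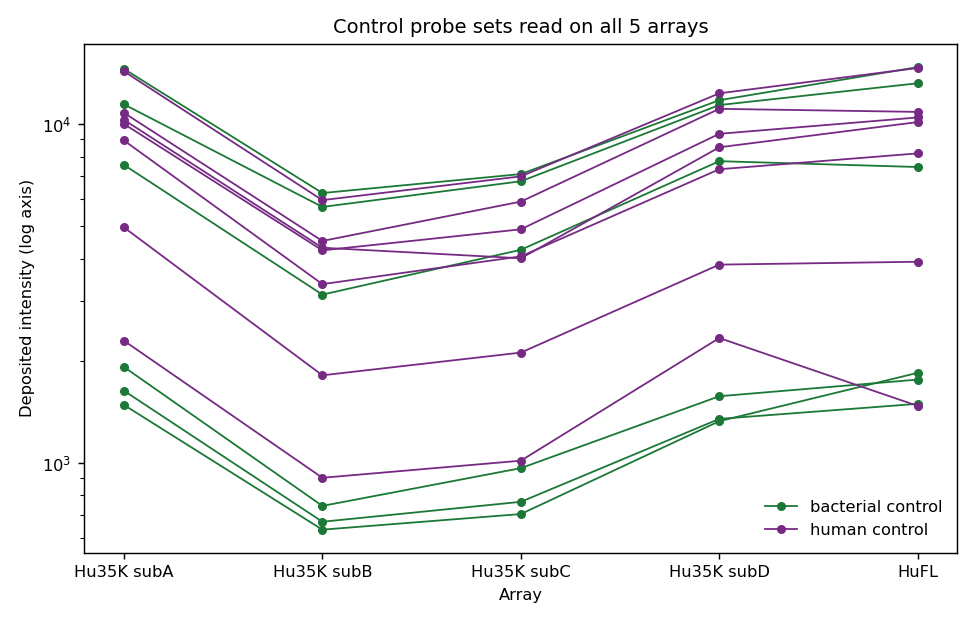
Each line is 1 of the 13 control probe sets above background on every array, green for bacterial and purple for human controls, with the deposited intensity on a log axis for each of the 5 arrays. The lines run nearly parallel, most of them lowest on subB and highest on subA or HuFL, a 2.46-fold range in the median.

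Controls for Bacillus transcripts, 15 probe sets on each array, gave 0 of 75 readings above background, and 6 yeast-named probe sets on 4 arrays gave 0 of 24. Controls for the opposite strand did not all stay below the bound. A probe set for the opposite strand of ACTB read 726 to 1614 and was above background on all 5 arrays. Another, for GAPDH, was above background on subD alone, at 408.

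Agreement of a gene's readings between array kinds was measured on 2856 genes with probe sets on both HuFL and a Hu35K array. The array and, for most genes, the probe set differ together here. Only 72 of these genes were above background on both kinds. The values for all 2856 therefore mostly describe genes not above background on both, and a gap cannot be assigned to the probe set. Across genes, which are not independent replicates, the scores from the 2 array kinds gave Spearman's rho of 0.24 and Pearson's r of 0.24 (permutation p 1e-05 each, two-sided, the smallest that 100000 permutations can give, Benjamini-Hochberg adjusted 1.2e-05). The median gap was 20.5 percentile points, and 1213 genes (42.5%) lay over 25 points apart. Without values of 0, 2511 genes gave a rho of 0.30, a median gap of 18.9 points and 40.3% over 25 points apart. Without probe sets of shared or special design, 1808 genes gave a rho of 0.14 and an r of 0.14. For 72 genes above background on both kinds, rho was 0.32 (permutation p 0.00565, adjusted 0.00616) and r was 0.18 (permutation p 0.121, adjusted 0.121). The adjustment covered the 12 relations computed in this family. Identical probe set IDs were read on HuFL and subA in 465 cases, with a rho of 0.38 over all of them, but only 3 of these were above background on both arrays, so this value describes readings mostly not above background.

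**Figure D3:**
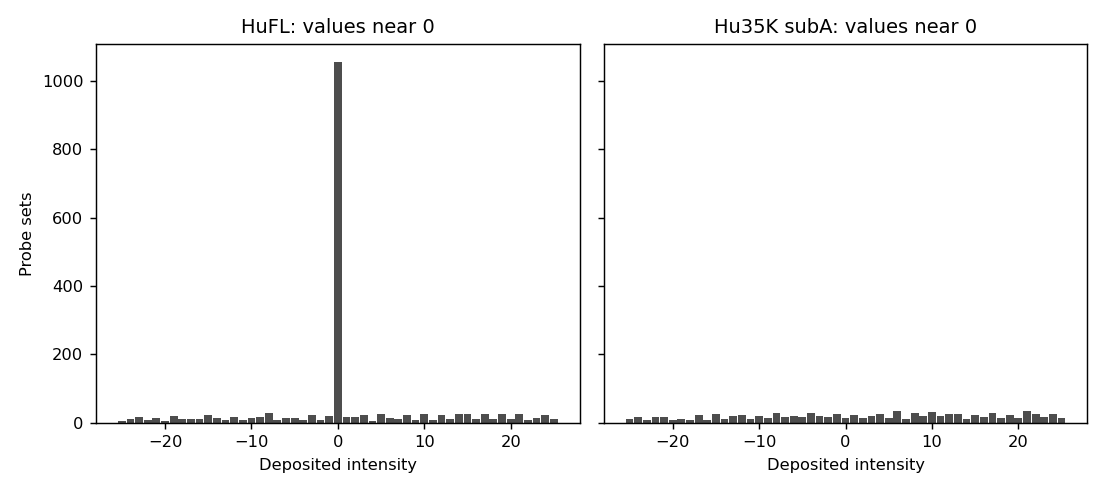
Bars give the number of probe sets (vertical axis) at each whole-number deposited intensity from -25 to 25 (horizontal axis) on HuFL and on Hu35K subA. HuFL has 1056 probe sets at 0 and at most 28 at any other value shown, and subA has 15 at 0.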

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

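No test in this part was chosen after its result was seen. Over the 5 arrays, 17 quantities, among them the shared control probe sets, were checked for a single array standing apart, meaning a gap to its nearest neighbour above 0.71 of the whole range, and 0 of the 17 met that mark. About 1 in 20 would by chance, and the controls move together across arrays, so they are not independent checks. The share of values at exactly 0 and the lowest value of each array were not among the 17. HuFL stood apart in both, as seen after the values were known. It had 14.8% of values at 0, against at most 1.26% on another array. Its lowest value was -14061, and the next lowest was -2684 on subA.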

How the results depend on the processing

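The bounds from the median of the values below 0 and without each array's lowest value, and the settings without values of 0, without control probe sets and without shared IDs, were chosen after the results were seen. Between 4.94% and 11.7% of probe sets per array passed the background bound, so most single genes have only a bound on their level. With 2 noise SDs the counts above background were 990 on subA, 807 on subB and 1020 on subC, and with the mirrored percentile 290, 325 and 391, while subD and HuFL stayed within 1.5 times. The bound from the median gave 1788, 1489, 2150, 2358 and 1200 on subA to subD and HuFL, because it weighs the farthest negative values less. Counts of list members above background moved by over 1.5 times in 6 of 32 lists with 2 noise SDs, in 2 with the mirrored percentile, in 18 with the bound from the median and in 3 without each array's lowest value. Leaving out 1 array at a time gave a control coefficient of variation from 29.5% to 44.2% and a brightness range from 2.08-fold to 2.47-fold, and the lowest of each came without subB, the dimmest array. Scaling to a trimmed mean left the size of the range at 2.45-fold but mostly turned the order of the arrays over, except that subA stayed above HuFL. That scaling sets arrays with mostly different probe sets to the same mean, so it need not equal their brightness. High lists numbered 14 to 18 of 32 under every alternative run, against 17. Low lists fell from 3 to 0 on HuFL alone and to 0 without probe sets of shared or special design, and the cause was not tested. The correlation of scores between array kinds stayed above 0 in all settings, from 0.14 without probe sets of shared or special design to 0.32 for genes above background on both kinds. No paired analysis was possible because all 5 arrays belong to 1 group.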

Other observations

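In this part, the test of blank readings was written before its result was seen, and the other tests were chosen only after the results were seen. Several bright genes lay outside the fixed lists. On subA the brightest readings outside them included NDRG2, a stress-responsive gene of muscle, at 10197, PDLIM5, a Z-disc protein, at 9879, and TMOD4, which caps thin filaments in muscle, at 9455. On subB they included CHCHD10, a mitochondrial protein, at 4328, and the muscle proteins SMPX at 3250, HSPB7 at 3198 and KLHL41 at 3009. CMYA5 read 7011 and 4916 and ANKRD23, a titin-binding protein, 6691 on subC. HSPB6, a small heat-shock protein of muscle, read 9599, MYOM1, which links myosin at the M-band, 8334 and PDLIM7 7766 on subD.

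Outside the contractile apparatus, TXNIP, a glucose-responsive inhibitor of thioredoxin and of glucose uptake, read 10313 on subD and 7190 on HuFL, above background on both. G0S2, an inhibitor of the lipase that breaks down stored fat, read 3561 on subC. TPT1, a growth-related protein found in most tissues, read 16209 on HuFL and 1527 on subB, while another subB probe set of this gene read -65. UBB, a ubiquitin gene, read 13635 and RPL39, a ribosomal protein gene, 12083 on HuFL. With no comparison pool, these values say nothing of a change with insulin resistance. All genes of both paragraphs except CMYA5, ANKRD23, CHCHD10, TXNIP and TPT1 were picked out after their values were seen.

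HuFL listed 1056 probe sets at exactly 0, 37.7 times the highest count at any other whole number from -25 to 25 (28 probe sets), which argues against rounding of small values. Probe sets named for X, Y or Z sequence records were at 0 in 43.7% (726 of 1661), the others in 6.04% (330 of 5468), among which K records reached 25.7% (9 of 35), V records 25% (5 of 20) and M records 12.7% (144 of 1132), so zeros were not particular to X, Y and Z. For 315 genes with a Hu35K probe set, the only HuFL probe set was at 0. Their median Hu35K score was 55.0, against 43.8 for 508 genes whose only HuFL probe set read within 50 of 0 but not 0. The difference was 11.2 percentile points (bootstrap 95% interval 6.01 to 17.5). Of the 315 genes, 58 were above background on a Hu35K array, the brightest being RPS27 (12073 on subA) and RPL41 (10905 on subD). The zeros may therefore be blank or failed readings and not measured absence. No biological explanation was tested, since the design gives none.

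The arrays differed 2.46-fold in brightness for 1 RNA pool. Unequal amounts of human RNA would move human controls and leave bacterial controls in place, but the difference between their shifts spanned 0.18 (log2) of a range of 1.30 over the arrays. After 1 factor per array was removed, the residual SD was 0.13 (log2), so a single factor for each array described these controls approximately. It was not exact for every control. The ratio of ACTB readings, 5 prime over 3 prime, was 5.56 on HuFL and 3.15 to 4.01 on the other arrays. For GAPDH this ratio ran from 1.32 to 1.43. What set the factor of each array, such as hybridisation, scanning or the submitters' scaling, was not tested, and no biological explanation applies to 1 RNA pool.

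Values below 0 came back on the same control probe sets. Of 15 Bacillus control probe sets, 6 were below 0 on all 5 arrays, where independent signs would give 1.25 (binomial upper point 4), which argues against random noise alone in these controls. The background bound assumes an even scatter around 0, and these controls did not fully meet that assumption. Among controls for the opposite strand, those of BioB-3, BioC-3 and BioC-5 were also below 0 on all 5 arrays. The lowest of these readings was -1084, for BioC-5 on subA. Other opposite-strand controls were mixed in sign or above 0 on all 5 arrays, and these controls were not tested. For probe sets other than controls it stayed open whether values far below 0 are a fixed property. Only 2 IDs shared by HuFL and subA read below the negative of the main HuFL bound, so the bound from the median of the values below 0 was used. Of 12 IDs below its negative, -400.3, 6 (50%) were below 0 on subA, against 64 of 175 (36.6%) that read within 100 of 0, an odds ratio of 1.73 (95% interval 0.442 to 6.77, Fisher's exact test, two-sided p 0.370). With so few IDs this cannot be told apart from no relation.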
